A study of Mus musculus with 8 samples.

How the data were processed

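The values analysed were array intensities of mouse probe sets, deposited by the authors as a table of 22690 probe sets by 8 arrays. Per the labels' protocols, total RNA was isolated with Trizol, copied into cDNA with an oligo-dT primer, transcribed in vitro into biotin-labelled cRNA and hybridized to Affymetrix mouse arrays. The deposited intensity values were on a linear scale, all positive, from 0.1 to 22736. The summarization software and any scaling or normalization between arrays are not given in the sources used here. From the values, the mean per array after trimming the outer 2% at each end ranged from 473 to 604, so no common scaling target was seen, and between 22.0 and 25.2% of values per array were below 16. No detection calls were used here, so a gene near the floor cannot be called undetected, and its fold change is understated.

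Each sample was placed in its group from its title. The 4 groups were sh-scr and sh-PRDM16 cells, each without or with 1 µM rosiglitazone, with 2 arrays per group. Gene names came from the platform annotation of the probe sets, checked against a RefSeq gene table (12369 of 12393 genes matched by Entrez identifier, 0 symbols changed). Of the probe sets, 20380 had 1 gene, 691 had several and 1555 were not listed in the annotation, and 64 were control probe sets. Only probe sets with 1 gene were named and tested. A gene was represented by its probe set with the highest mean over all arrays, and where named genes had several probe sets these were also tested each on its own. Of the 12393 genes measured, the 25% with the lowest mean were left out, which left 9294.

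Values were transformed as log2(intensity + 16), so a fold change understates the change of dim genes. The medians of the arrays differed by at most log2 0.38, under the limit of 0.5 set in advance for taking the table as not normalized, so the deposited scale was kept as the main setting, with median-centred and quantile-normalized arrays as alternatives. limma 3.58.1 (lmFit and eBayes, R 4.3.3) was fitted once to all 8 arrays with a mean per group, which left 4 residual degrees of freedom and a prior of 5.31. The 5 contrasts were rosiglitazone in sh-scr cells, rosiglitazone in sh-PRDM16 cells, sh-PRDM16 against sh-scr without and with rosiglitazone, and the interaction, which is the difference between the 2 rosiglitazone responses. Tests were two-sided with Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. A gene was said to rise or fall only if it passed on the deposited scale.

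The 21 gene lists were fixed before the data were examined: brown-fat-selective, beige, white-fat-selective and general adipocyte genes, PPAR targets, fatty acid oxidation, respiratory chain, TCA cycle, lipogenesis, extracellular matrix and fibroblast, interferon response, inflammatory cytokines, ER stress and amino acid response, cell cycle, housekeeping genes, and markers of macrophages and leukocytes, endothelium, smooth muscle and pericytes, skeletal muscle, preadipocytes, and mesothelium and mammary epithelium. They were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over all 105 tests of lists and contrasts, of which 50 passed. With an estimated correlation 0 passed (12 at an unadjusted p under 0.05). In fry, a further alternative that asks only whether a set's genes move one way on balance, 55 passed. Counts adjusted over the list alone apply Benjamini-Hochberg to the members only.

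The named genes follow a rule set in advance: in each contrast the 10 largest rises and 10 largest falls among genes past the threshold whose 2 groups do not overlap, a fixed set of thermogenic and adipocyte genes in every contrast, and the 4 members with the largest change in each list described. Some names were left out for length.

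Overlaps of calls were set against independent lists, and the covariance of changes across genes, where 2 contrasts share arrays, against 100 simulated sets of unchanged groups. Simulated data took the gene means and spreads of these arrays, with genes drawn independently and no shift of all genes. For the rosiglitazone comparison in sh-scr cells, 200 of 9294 genes were changed in each of 10 rounds. Of genes changed by log2 1, 93.6% were recovered, of those changed by log2 2, 99.9%, and 6.57% of calls were false. The fatty acid oxidation list, shifted by log2 0.5, was called in all 10 rounds with either correlation, and 5 unshifted lists were called over all rounds. In the data the estimated correlation of that list was 0.63. The simulation, without such correlation, therefore does not show the power of the estimated-correlation test here.

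The alternatives tried were quantile and median scaling, no filter and a filter on the lower 50% of genes, the mean of all probe sets of a gene, a trended variance prior, pseudocounts of 1 and 64, the replicate number as a block, fits of only the 4 arrays compared, and leaving out each array in turn, where the lone array of a group is assumed to vary like those of the other groups. Control probe sets, probe sets with several genes and those without annotation were left out of the gene tests. The figures were drawn with matplotlib 3.10.9.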

Results

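RNA was measured in adipocytes that had been differentiated in culture from SV (stromal-vascular) cells of inguinal white fat, a subcutaneous depot, of male C57BL/6J mice. The cells carried either a control shRNA named sh-scr or an shRNA named for PRDM16, a transcriptional co-regulator of brown fat genes. Each line was kept without or with 1 µM rosiglitazone, a thiazolidinedione drug that activates the nuclear receptor PPARγ. The 4 resulting groups had 2 arrays each, 8 arrays in all. The design asks which part of the response to a PPARγ agonist runs through PRDM16. Groups are called untreated sh-scr, treated sh-scr, untreated sh-PRDM16 and treated sh-PRDM16 below.

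The median array intensity was 127 and 136 in the untreated sh-scr arrays, 108 and 101 in the treated sh-scr arrays, 122 and 105 in the untreated sh-PRDM16 arrays, and 109 and 121 in the treated sh-PRDM16 arrays. Across probe sets, replicate arrays correlated at r = 0.991 in each group, against at most 0.984 with an array of another group, and probe sets are not independent replicates. Between 121 and 128 of 22690 probe sets held identical values in both arrays of a group, so no array was a copy of another. The 3′ minus 5′ difference of the beta-actin control probe sets, a sign of RNA integrity, was highest in the treated sh-scr arrays, at log2 0.38 and 0.49, and lay between 0.25 and 0.34 in the other arrays. That of the Gapdh control probe sets was higher in the 4 treated arrays (log2 -0.35 to -0.33) than in the 4 untreated arrays (-0.45 to -0.40), and highest in treated sh-PRDM16 replicate 2. The labels call the arrays biological replicates without saying whether they came from separate cultures or animals, so p-values measure only the spread between these arrays. With 2 arrays per group, the number of arrays limits the precision, and the median standard error of a log2 change was 0.15. No probe set is paired with Prdm16 in the annotation used here, so the RNA of the targeted gene was not analysed here and the sh-PRDM16 groups rest on their labels alone. Otop1, Cpt1b and Adrb3, also chosen in advance, were likewise not analysed here.

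In sh-scr cells, rosiglitazone raised thermogenic and fatty acid oxidation genes. Ucp1, the uncoupling protein of brown fat mitochondria, went from an intensity of 12.9 ± 10.9 (SD, n = 2) to 1309 ± 18.7, a log2 change of 5.57 (SE 0.23, adjusted p = 1.2e-06). Cidea, a lipid droplet protein abundant in brown fat, went from 19.1 ± 7.2 to 548 ± 52.4 (log2 4.02, SE 0.16, adjusted p = 1.2e-06). Elovl3, a fatty acid elongase of brown fat, rose by log2 4.28 from 238 ± 44.7 to 4859 ± 4.6. The genes with the largest rises after Ucp1 were Car4, a carbonic anhydrase, at log2 5.22, Aadac, an esterase, at 4.69, and Acaa1b, a peroxisomal thiolase, at 4.50. 2610528A11Rik (4.15), Pdk4 (3.51), a kinase that restrains pyruvate oxidation, Serpinb9g (3.14) and Cyp4b1 (3.03) completed the 10 largest. The largest falls were those of Mup3 (log2 -3.05), Cyp2f2 (-2.88), Igfals (-2.83), the serum amyloid A genes Saa1 (-2.79) and Saa4 (-2.26), Sncg (-2.77), Lep (-2.30), which encodes leptin, Atf7ip2 (-2.21), Srgn (-2.01) and Lratd1 (-1.94). Acaa1b, Mup3 and Saa1 have close paralogs that can share hybridization, so the signal of their probe sets is uncertain as to the gene.

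Of 26 brown-fat-selective genes tested in sh-scr cells, 15 rose and 4 fell with rosiglitazone (15 and 6 adjusted over the list alone, 18 and 1 on median-centred arrays). Their median lay log2 1.08 above that of all genes (adjusted p = 1.4e-17 with a preset correlation, adjusted p = 0.241 with an estimated correlation). Fgf21 (log2 3.02), Fabp3 (2.56), the cytochrome c oxidase subunits Cox7a1 (2.06) and Cox8b (2.02), the transcription factor Ppara (2.05) and the co-activator Ppargc1a (1.46) were among those that rose. Of 22 PPAR target genes, 15 rose and 1 fell (the same counts adjusted over the list alone), with a median 1.26 above all genes (adjusted p = 3.5e-21 preset, adjusted p = 0.395 with an estimated correlation), led by Acaa1b, Pdk4, Fgf21 and Ehhadh (2.89). Of 24 fatty acid oxidation genes, 18 rose and 1 fell (19 and 1 adjusted over the list alone), with Acaa2 (1.51) and Hadhb (1.22) after Ehhadh (median 0.99 above all genes, adjusted p = 2.8e-24 preset, adjusted p = 0.395 with an estimated correlation). The respiratory chain list had 15 of 55 genes up and 0 down, and the TCA cycle list 9 of 21 up and 0 down (12 and 10 up adjusted over the list alone). Both were called with the preset correlation (adjusted p = 7.0e-21 and 3.7e-13, and adjusted p = 0.449 for each with an estimated correlation). On median-centred arrays 50 and 19 of their genes rose.

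Genes of adipocytes in general rose in part in sh-scr cells. Of 23 tested, 11 rose and 1 fell with rosiglitazone (11 and 2 adjusted over the list alone; adjusted p = 6.6e-11 preset, adjusted p = 0.449 with an estimated correlation). Cidec, a lipid droplet protein, rose by log2 2.55 and Retsat by 1.43, while Dgat2, which makes triglyceride, fell by 1.24. Fabp4 (log2 -0.08, adjusted p = 0.644) and Adipoq (-0.08, adjusted p = 0.635) did not pass the test at mean intensities of 21050 to 22260 and 14200 to 14980, near the top of the range of the arrays, and the mean of the 4 Fabp4 probe sets gave a rise of 0.47 (adjusted p = 0.040). Pparg itself did not pass (-0.39, adjusted p = 0.0532). Of 14 white-fat-selective genes, 1 rose and 5 fell (the same counts adjusted over the list alone), Sncg, Lep, Retn (-1.36), Wfdc21 (-1.33) and Dpt (-1.27) among them, but the list as a set did not pass (adjusted p = 0.161). Of 10 beige markers, 3 rose (Cited1 2.21, Slc27a1 1.71 and P2rx5 0.70) and 4 fell (the same counts adjusted over the list alone, 3 and 1 on median-centred arrays), and the set did not pass (adjusted p = 0.0591). Of 18 lipogenesis genes, 2 rose, with Acacb at 2.57, and 7 fell (2 and 7 adjusted over the list alone, 4 and 4 on median-centred arrays, set adjusted p = 0.377).

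Inflammatory, matrix and stromal genes fell with rosiglitazone in sh-scr cells, where 2991 of all 9294 genes tested fell. The median change of all genes there was log2 -0.31, so part of these falls is shared with genes in general. Of 19 inflammatory cytokine genes, 15 fell and 0 rose (the same counts adjusted over the list alone), among them Lcn2 (log2 -1.60), Orm1 (-1.56) and Il6 (-1.21), and 10 fell on median-centred arrays (adjusted p = 0.00063 preset, adjusted p = 0.449 with an estimated correlation). Of 31 extracellular matrix and fibroblast genes, 19 fell (21 adjusted over the list alone), with Pdgfrb at -0.99 and Lum at -0.91, and 9 fell on median-centred arrays (adjusted p = 0.0031 preset, adjusted p = 0.693 with an estimated correlation). Of 12 smooth muscle and pericyte genes 9 fell, with Actg2 at -1.56 and Myh11 at -1.35, and of 14 preadipocyte genes 10 fell (9 and 10 adjusted over the list alone, 5 and 7 on median-centred arrays). Both sets were called with the preset correlation (adjusted p = 0.0087 and 0.012, adjusted p = 0.449 and adjusted p = 0.615 with an estimated correlation). Macrophage and leukocyte markers had 8 of 16 genes down (10 adjusted over the list alone, set adjusted p = 0.0611), 2 of them on median-centred arrays. Endothelial genes had 7 of 12 down (7 adjusted over the list alone, set adjusted p = 0.113), with Emcn at -1.22, and 1 on median-centred arrays. Interferon response genes had 4 of 26 down (4 adjusted over the list alone, 0 on median-centred arrays, set adjusted p = 0.369). ER stress and amino acid response genes had 9 of 19 down, Pdia4 (-0.99) among them, and 1 up, Dnajb9 at 0.84 (10 and 1 adjusted over the list alone, 6 and 2 on median-centred arrays, set adjusted p = 0.246). Of 10 housekeeping genes 2 rose, Tfrc (0.45) and Pgk1 (0.41), and Gusb fell by 0.70 (0 and 1 adjusted over the list alone, set adjusted p = 0.161).

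In all, 483 genes rose and 2991 fell with rosiglitazone in sh-scr cells of 9294 tested (limma, adjusted p under 0.05). The median change of all genes was log2 -0.31 there, so list medians are given relative to all genes and the split of calls depends on the scale. With each array centred on its median, 1322 rose and 1103 fell, with quantile normalization 1217 rose and 1379 fell, and 476 rises and 1087 falls were called on all 3 scales. The 3474 calls became 1486 without untreated sh-scr replicate 1, 1217 without untreated sh-scr replicate 2 and 1084 without treated sh-scr replicate 2.

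**Figure D1:**
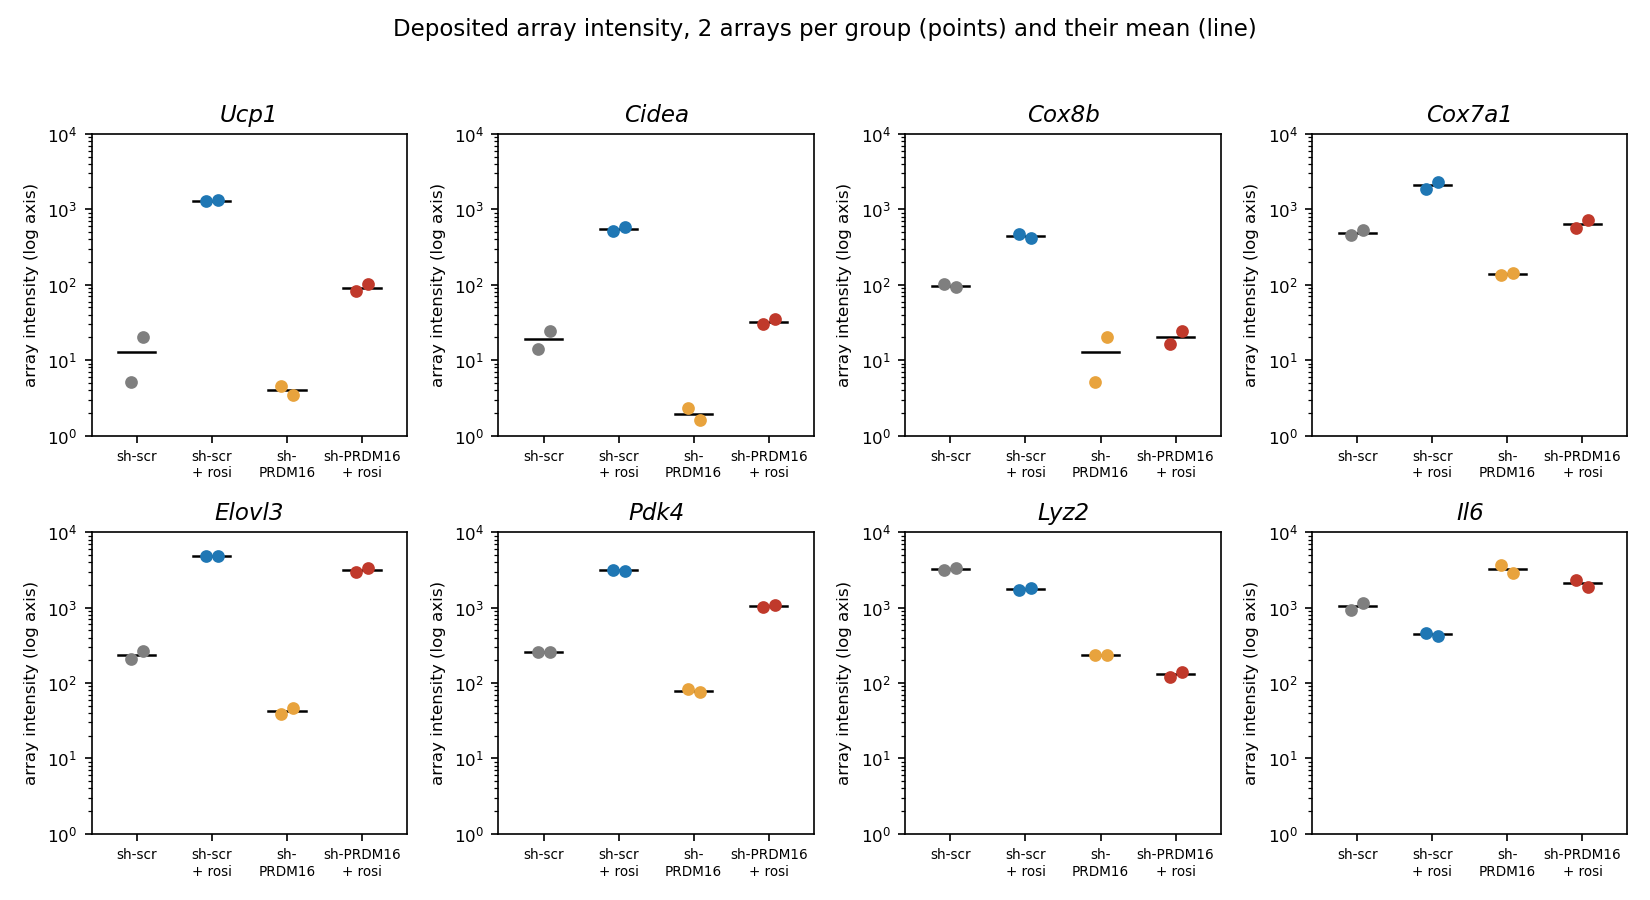
Deposited intensity (log axis) of 8 genes in the 4 groups, with a point for each of the 2 arrays and a line at their mean. Ucp1 reached 1309 in treated sh-scr and 91.5 in treated sh-PRDM16 arrays, Lyz2 was 3228 in untreated sh-scr and 235 in untreated sh-PRDM16 arrays, and the lowest values lie near the floor.

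In cells with the PRDM16 shRNA, rosiglitazone also raised PPAR target and oxidation genes. Elovl3 rose by log2 5.75 (SE 0.16, adjusted p = 1.2e-07), from 43.0 ± 5.6 (SD, n = 2) to 3161 ± 334, and Acaa1b by 5.66 (SE 0.16, adjusted p = 1.2e-07). Car4 (5.28), Aadac (4.71), Glyat (4.17), Krt36 (3.92), the glycogen synthase Gys2 (3.85), Acot3 (3.83), Cidec (3.79) and Serpinb9g (3.74) completed the 10 largest rises. Pdk4 rose by 3.48, Fabp3 by 2.93, Cox7a1 by 2.09, Ppara by 1.75, Angptl4 by 1.54 and Ppargc1a by 1.25. Ucp1 rose by 2.42 (SE 0.23, adjusted p = 0.00016), to 91.5 ± 13.5, and Cidea by 1.43 (SE 0.16, adjusted p = 0.00051), to 32.5 ± 3.7. Cox8b did not pass, at log2 0.38 (adjusted p = 0.342). Saa1 (-2.51), Esm1 (-2.47), Lep (-2.26), Mup3 (-2.22), Sncg (-1.96), Saa4 (-1.90), Srgn (-1.45), Mmp13 (-1.41) and Saa2 (-1.40) had the largest falls that held on all 3 scales. Acot3, Saa1, Saa2 and Mup3 have close paralogs, with the same uncertainty of the probe set.

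Among the fixed lists in sh-PRDM16 cells, rosiglitazone raised 23 of 24 fatty acid oxidation genes, 17 of 22 PPAR targets, 39 of 55 respiratory chain genes, 17 of 21 TCA cycle genes and 13 of 23 general adipocyte genes, and lowered 0 in each. Adjusted over the list alone, 23, 18, 51, 19 and 16 rose. All 5 sets were called with the preset correlation (largest adjusted p = 5.6e-12), with adjusted p = 0.395 for the first 2 and adjusted p = 0.449 for the others with an estimated correlation. Of 26 brown-fat-selective genes 12 rose and 0 fell (13 and 1 adjusted over the list alone), with a median 0.40 above all genes (adjusted p = 4.8e-07 preset, adjusted p = 0.395 with an estimated correlation), and the same 12 genes rose in sh-scr cells. Lipogenesis genes rose in 7 of 18 cases (13 adjusted over the list alone; Acacb 3.03, Me1 1.28; adjusted p = 3.8e-06 preset, adjusted p = 0.449 with an estimated correlation). Inflammatory cytokine genes fell in 5 of 19 cases (8 adjusted over the list alone, 8 on median-centred arrays; Lcn2 -0.86, Cxcl12 -0.84; adjusted p = 1.0e-05 preset, adjusted p = 0.395 with an estimated correlation). Of 31 matrix genes 3 fell, among them Mmp3 (-0.97), and of 12 smooth muscle genes 5 fell, among them Myh11 (-1.12). These became 9 and 6 adjusted over the list alone, and 16 and 6 on median-centred arrays (adjusted p = 3.0e-05 and 0.00098 preset, adjusted p = 0.600 and adjusted p = 0.449 with an estimated correlation). White-fat-selective genes had 1 rise and 5 falls in 14 (4 and 5 adjusted over the list alone, 3 and 5 on median-centred arrays, set adjusted p = 0.134), with Lep, Sncg and Retn (-1.13) among the falls, and 0 of 24 cell cycle genes passed in limma (0 adjusted over the list alone, 1 at an unadjusted p under 0.05). Of 16 macrophage and leukocyte markers 2 fell, Lyz2 (-0.78) and Lyz1 (-0.66), or 7 adjusted over the list alone and 4 on median-centred arrays (adjusted p = 0.00028 preset, adjusted p = 0.395 with an estimated correlation). Endothelial genes had 3 of 12 down, among them Tek (-1.08), and preadipocyte genes 2 of 14, Fap (-0.65) and Klf2 (-0.55), or 4 each adjusted over the list alone, and 3 and 8 on median-centred arrays (adjusted p = 0.0013 and 0.0032 preset, adjusted p = 0.395 and adjusted p = 0.594 with an estimated correlation).

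In these cells 937 genes rose and 308 fell with rosiglitazone, at a median change of all genes of log2 0.00. Median-centred arrays gave 1347 and 917, quantile normalization 1230 and 1257, and 902 rises and 296 falls were called on all 3 scales. The 1245 calls became 798 without untreated sh-PRDM16 replicate 2, 795 without treated sh-PRDM16 replicate 1 and 641 without treated sh-PRDM16 replicate 2.

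The comparison of the 2 rosiglitazone responses, which share no array, showed how far they ran together. Across the 9294 genes, which are not independent replicates, the log2 changes correlated at r = 0.736 with a slope of 0.735 for sh-PRDM16 on sh-scr cells. Of the 483 genes that rose in sh-scr cells, 413 also rose in sh-PRDM16 cells, against 48.7 for independent lists. In both, 262 genes fell, against 99.1. On median-centred arrays 952 rose in both, against 191.6, and 519 fell in both, against 108.8. The test of the difference called 62 genes, 56 with a more positive and 6 with a more negative change in sh-PRDM16 cells, out of 2365 with an unadjusted p under 0.05. The median of this difference over all genes was log2 0.33. Median-centred arrays left 5 genes, Ucp1, Cidea, Lama5 and Arhgap20 as more negative and Dgat2 as more positive, and quantile normalization also left 5, with Wnk4 in place of Lama5. In limma without the filter on low values 0 of 12393 genes passed (2402 at an unadjusted p under 0.05), and without untreated sh-PRDM16 replicate 2 also 0 of 9294 (1453 unadjusted). Leaving out treated sh-PRDM16 replicate 2 left 14, treated sh-scr replicate 2 left 24, untreated sh-scr replicate 2 or 1 left 27 or 37, and untreated or treated sh-PRDM16 replicate 1 left 29 or 40.

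Ucp1 responded less in sh-PRDM16 cells by log2 -3.15 (SE 0.32, adjusted p = 0.0094) and Cidea by -2.59 (SE 0.23, adjusted p = 0.0094), both called on all 3 scales. Without the filter on low values both had adjusted p = 0.0562, with a pseudocount of 1 the differences shrank to log2 -2.61 for Ucp1 and -1.31 for Cidea (adjusted p = 0.164 for both), and without untreated sh-PRDM16 replicate 2 both had adjusted p = 0.0900, the direction being kept. Their untreated intensities, 12.9 and 4.0 for Ucp1 and 19.1 and 1.95 for Cidea in sh-scr and sh-PRDM16 cells, lay near the floor, so the size of the difference depends on the pseudocount. Dgat2 differed by 1.61 (SE 0.19, adjusted p = 0.0094), since it fell in sh-scr cells and did not pass in sh-PRDM16 cells (0.37, adjusted p = 0.101), and lost its call without the filter (adjusted p = 0.0562) and without untreated sh-PRDM16 replicate 2 (adjusted p = 0.0900). Cox8b differed by -1.64 and missed the threshold (adjusted p = 0.0616). For Cox7a1 (0.03, SE 0.24), Pdk4 (-0.03, SE 0.17), Ppargc1a (-0.20, SE 0.18) and Ppara (-0.30, SE 0.31) no difference in response passed. Elovl3 differed by 1.48 and Cidec by 1.24 on the deposited scale (adjusted p = 0.0331 for both), and neither passed on median-centred arrays (adjusted p = 0.104 and 0.0606). As sets, brown-fat-selective genes had a median of log2 -0.18 relative to all genes for the difference and a mean of -0.40 (adjusted p = 9.5e-06 preset, adjusted p = 0.395 with an estimated correlation), while their median not taken relative to all genes had the opposite sign, 0.15. With 50% of genes filtered the call was lost (median -0.044, adjusted p = 0.331). By gene, 1 was called as more positive and 2 as more negative (4 and 4 adjusted over the list alone). Lipogenesis and general adipocyte genes lay 0.31 and 0.29 above all genes (adjusted p = 9.8e-06 and 0.00044 preset, adjusted p = 0.449 and adjusted p = 0.615 with an estimated correlation), with 1 and 2 genes called (12 and 14 adjusted over the list alone). PPAR target and fatty acid oxidation genes lay 0.21 and 0.11 above (adjusted p = 0.0083 and 0.012 preset, adjusted p = 0.615 and adjusted p = 0.771 with an estimated correlation; 1 and 0 genes called, 8 and 8 adjusted over the list alone). Interferon response genes had a median of log2 -0.32 relative to all genes, and 0.01 on its own (0 genes called, 0 adjusted over the list alone; adjusted p = 0.0023 preset, adjusted p = 0.625 with an estimated correlation, adjusted p = 0.412 on median-centred arrays). Without untreated sh-PRDM16 replicate 2 this median turned to 0.13 (adjusted p = 0.0815).

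**Figure D2:**
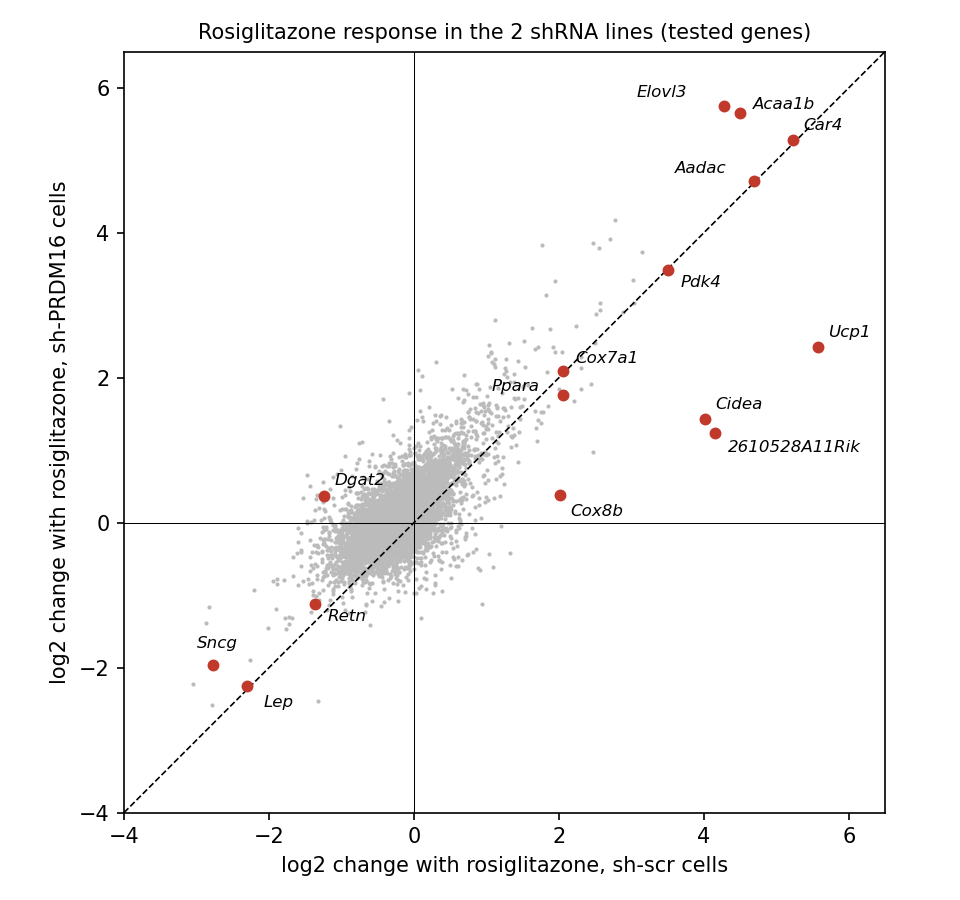
Log2 change with rosiglitazone of each tested gene (grey points) in sh-PRDM16 cells, vertical axis, against sh-scr cells, horizontal axis, on log2 of intensity plus 16, with chosen genes in red and equal change as a dashed line. Ucp1 (5.57 against 2.42) and Cidea (4.02 against 1.43) lie below the line, Pdk4 (3.51 against 3.48) and Cox7a1 (2.06 against 2.09) on it.

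In treated cells, the sh-PRDM16 line had far less RNA of Cox8b, Ucp1 and Cidea than the sh-scr line. Cox8b was 444 ± 35.6 (SD, n = 2) in treated sh-scr and 20.3 ± 5.6 in treated sh-PRDM16 arrays, a log2 change of -3.67 (SE 0.23, adjusted p = 3.0e-05). Ucp1 was lower by log2 -3.63 (SE 0.23, adjusted p = 2.8e-05) and Cidea by -3.54 (SE 0.16, adjusted p = 6.7e-06). Cox7a1 (-1.69), Pdk4 (-1.56), Ppargc1a (-1.47), Ppara (-1.34) and Elovl3 (-0.62) also fell, whereas Fabp3 (-0.37, adjusted p = 0.115), Pparg (-0.30, adjusted p = 0.166), Adipoq (-0.02), Fabp4 (0.02) and Angptl4 (0.10) did not pass. Of 26 brown-fat-selective genes 10 fell and 3 rose (12 and 4 adjusted over the list alone), with a median log2 -0.56 relative to all genes (adjusted p = 2.0e-07 preset, adjusted p = 0.395 with an estimated correlation). In the same arrays 15 of 16 macrophage and leukocyte markers fell and 22 of 24 cell cycle genes rose.

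Genes of other metabolic lists also fell in treated sh-PRDM16 cells, in numbers that depend on the scale. Fatty acid oxidation had 9 of 24 genes down and 2 up, PPAR targets 9 of 22 down and 1 up, and general adipocyte genes 7 of 23 down and 1 up, with Ehhadh (log2 -2.21), Pck1 (-1.87), a gluconeogenic and glyceroneogenic enzyme, Pdk4 (-1.56), Adig (-1.35) and Plin5 (-1.31) falling most. Adjusted over the list alone, 13, 9 and 7 fell, and on median-centred arrays 20, 15 and 16 fell. These sets were called with the preset correlation (adjusted p = 5.5e-10, 3.2e-09 and 3.4e-08, adjusted p = 0.449, adjusted p = 0.449 and adjusted p = 0.493 with an estimated correlation). Lipogenesis had 5 of 18 genes down, led by Thrsp (-2.12), and 1 up (7 and 1 adjusted over the list alone, 8 and 1 on median-centred arrays; adjusted p = 0.00021 preset, adjusted p = 0.541 with an estimated correlation). The respiratory chain and TCA cycle lists had 2 genes down each, of 55 and 21, and 22 and 15 on median-centred arrays (2 and 1 adjusted over the list alone; adjusted p = 2.2e-07 and 7.2e-06 preset, adjusted p = 0.615 and adjusted p = 0.600 with an estimated correlation). Of 14 white-fat-selective genes 3 fell, Lep (-2.01), Retn (-1.72) and Slc7a10, and 1 rose (4 and 2 adjusted over the list alone, 5 and 1 on median-centred arrays; adjusted p = 0.0193 preset, adjusted p = 0.618 with an estimated correlation, adjusted p = 0.0783 on median-centred arrays). Of 10 beige markers 2 fell and 1 rose (the same counts adjusted over the list alone, set adjusted p = 0.230). Of 26 interferon response genes 2 fell, Psmb8 (-0.83) and Psmb9 (-0.79), which encode immunoproteasome subunits (2 adjusted over the list alone; adjusted p = 0.0067 preset, adjusted p = 0.692 with an estimated correlation, adjusted p = 0.0709 on median-centred arrays).

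The largest falls of treated sh-PRDM16 cells outside the thermogenic genes were those of macrophage genes. The lysozyme genes Lyz1 and Lyz2 had log2 changes of -4.06 and -3.62, Lyz2 going from 1772 ± 68.3 to 130 ± 12.3, and Cd5l (-3.40), Clec4d (-3.13), Mmp12 (-2.94), the complement gene C1qa (-2.85) and Tyrobp (-2.83) completed the 10 largest. Lyz1 and Lyz2 are near-identical, so their signals are uncertain as to the gene. Of the 16 macrophage and leukocyte markers, 15 fell and 0 rose (15 and 0 adjusted over the list alone), with a median log2 -2.33 relative to all genes (adjusted p = 4.3e-26 preset, adjusted p = 0.170 with an estimated correlation). Csf1r, the receptor of a macrophage growth factor, was the exception (0.06, adjusted p = 0.812).

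Cell division genes and Il6 were higher in treated sh-PRDM16 cells. Of 24 cell cycle genes, 22 rose and 0 fell (24 and 0 adjusted over the list alone), with a median 0.94 above all genes (adjusted p = 5.4e-15 preset, adjusted p = 0.449 with an estimated correlation), led by Cdc20 (log2 1.86), Ccnb2 (1.69), Aurka (1.55) and Birc5 (1.45). Il6, a cytokine, rose by 2.21 (SE 0.18, adjusted p = 0.00013), from 441 ± 29.2 to 2108 ± 337, followed by Hs3st1 (2.12), the phosphatase Dusp9 (2.10), Pmaip1 (1.97), Apoc4 (1.87), Krt19 (1.85), Acta1 (1.77) and Tnmd (1.73). Of 19 inflammatory cytokine genes 6 rose and 0 fell (7 and 1 adjusted over the list alone, 5 and 3 on median-centred arrays), with Ptgs2 at 1.14, and the set did not pass (adjusted p = 0.258). Of 31 matrix genes 3 rose and 1 fell (4 and 3 adjusted over the list alone, 3 and 3 on median-centred arrays, set adjusted p = 0.632). Smooth muscle genes had 3 of 12 up, with Actg2 at 1.21 and Cnn1 at 1.16, and 1 down (the same counts adjusted over the list alone, set adjusted p = 0.0925). Acta1 was the member of the 7 skeletal muscle genes that rose (2 adjusted over the list alone, set adjusted p = 0.237), and Krt19 that of the 5 mesothelial and epithelial genes (1 adjusted over the list alone, set adjusted p = 0.216).

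In treated cells 981 genes rose and 429 fell with sh-PRDM16, at a median change of all genes of log2 0.15. Median-centred arrays gave 1146 and 1141, quantile normalization 1160 and 1162, and 831 rises and 424 falls were called on all 3 scales. The 1410 calls became 896 and 492 without treated sh-scr replicate 1 or 2, 637 and 577 without treated sh-PRDM16 replicate 1 or 2, 803 with no filter on low values and 2609 with a trended variance prior. Without treated sh-PRDM16 replicate 2, 41.2% of the 577 calls were rises, against 69.6% of the 1410.

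Without rosiglitazone, the sh-PRDM16 line already had less RNA of adipocyte and lipid genes. Of 23 general adipocyte genes, 19 fell and 0 rose (22 and 0 adjusted over the list alone), with a median log2 -0.82 relative to all genes (adjusted p = 7.2e-13 preset, adjusted p = 0.449 with an estimated correlation). Gpd1, Cidec (log2 -1.98), Adig (-1.97) and Pck1 (-1.55) fell most, Pparg fell by 0.99 from 3175 ± 83.4 (SD, n = 2) to 1602 ± 198, and Adipoq fell by 0.52. Of 18 lipogenesis genes 16 fell and 0 rose, led by Thrsp (-2.77) and Acss2 (-1.90), and of 22 PPAR targets 17 fell and 0 rose (16 and 20 down, 0 and 1 up, adjusted over the list alone; adjusted p = 1.0e-10 and 5.7e-11 preset, adjusted p = 0.395 for both with an estimated correlation). Fatty acid oxidation had 22 of 24 genes down, the respiratory chain 33 of 55 and the TCA cycle 16 of 21, with 0 up in each (22, 47 and 18 adjusted over the list alone). Ehhadh fell by 2.24, Acaa2 by 1.31, Ndufb3 by 1.06 and Pcx by 1.15 (adjusted p = 1.4e-11, 1.9e-10 and 4.8e-07 preset, adjusted p = 0.449, adjusted p = 0.581 and adjusted p = 0.570 with an estimated correlation). In these arrays 14 of 16 macrophage markers fell and 15 of 24 cell cycle genes rose.

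Of 26 brown-fat-selective genes 10 fell and 1 rose in untreated sh-PRDM16 cells (the same counts adjusted over the list alone), with a median log2 -0.17 relative to all genes (adjusted p = 0.0130 preset, adjusted p = 0.529 with an estimated correlation). Elovl3 (log2 -2.10), Cox8b (-2.03), Plin5 (-1.82), Cox7a1 (-1.72), Pdk4 (-1.53), Ppargc1a (-1.27), Ppara (-1.04) and Cidea (-0.95) fell, Eva1a rose (1.14), and Ucp1, near the floor in both lines, did not pass (-0.48, adjusted p = 0.187). Of 14 white-fat-selective genes 6 fell and 0 rose (11 and 0 adjusted over the list alone; Lep -2.05, Retn -1.95, Slc7a10 -0.98; adjusted p = 0.0021 preset, adjusted p = 0.581 with an estimated correlation). Retn, which encodes resistin, had 3910 ± 616 in untreated sh-scr, 1000 ± 142 in untreated sh-PRDM16, 1506 ± 122 in treated sh-scr and 449 ± 68.9 in treated sh-PRDM16 arrays. Agt, a further white fat gene chosen in advance, did not pass in any of the 5 tests.

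The 10 largest falls without rosiglitazone held 9 macrophage genes beside Thrsp. Lyz1 (log2 -4.06), Lyz2 (-3.69), Clec4d (-3.66), C1qc (-3.42), Cd5l (-3.34), Tyrobp (-3.24), C3ar1 (-2.88), Mmp12 (-2.79) and C1qa (-2.75) were these, Lyz2 being 3228 ± 114 in sh-scr and 235 ± 1.1 in sh-PRDM16 arrays. The macrophage and leukocyte list had 14 of 16 genes down and 0 up (16 and 0 adjusted over the list alone), with a median log2 -2.25 relative to all genes (adjusted p = 1.3e-17 preset, adjusted p = 0.194 with an estimated correlation). Il6 (1.62) and Cenpe (1.53), a mitotic motor protein, had the largest rises, followed by Aif1l (1.40), Crabp1 (1.36), the cytokine Il11 (1.28), Tll1 (1.28), the hyaluronan synthase Has1 (1.23), Mapk13 (1.18), Wdr90 (1.18) and Eva1a. Cell cycle genes had 15 of 24 up and 0 down (22 and 0 adjusted over the list alone, 24 and 0 on median-centred arrays), with a median 0.85 above all genes (adjusted p = 2.7e-25 preset, adjusted p = 0.395 with an estimated correlation), led by Plk1 (1.09) and Aurka (1.04). All 15 also rose in treated sh-PRDM16 cells. Of 19 inflammatory cytokine genes 3 rose and 4 fell (4 and 5 adjusted over the list alone, 5 and 2 on median-centred arrays, set adjusted p = 0.110).

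Without rosiglitazone 185 genes rose and 1439 fell with sh-PRDM16, at a median change of all genes of log2 -0.16. Median-centred arrays gave 818 and 1170, quantile normalization 979 and 1174, and 184 rises and 1110 falls were called on all 3 scales. The 1624 calls became 1018 and 665 without untreated sh-scr replicate 1 or 2 and 764 without untreated sh-PRDM16 replicate 2. The changes with and without rosiglitazone, which share no array, correlated across genes at r = 0.687 with a slope of 0.715. Of the called genes 142 rose in both, against 19.5 for independent lists, and 374 fell in both, against 66.4. On median-centred arrays 488 rose in both, against 100.9, and 762 fell in both, against 143.6.

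**Figure D3:**
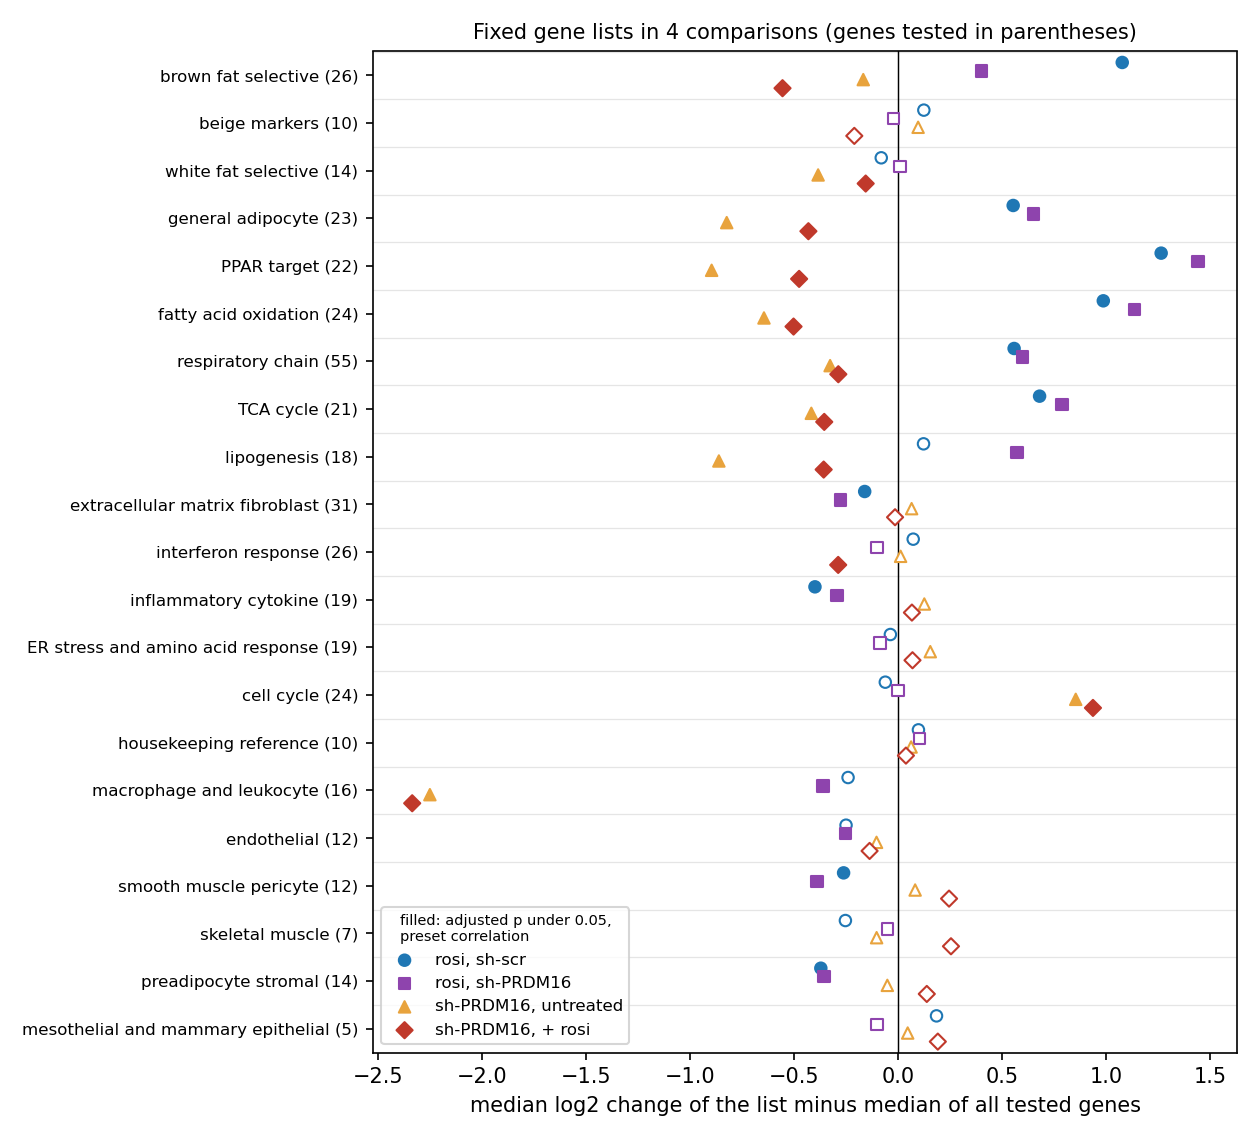
Median log2 change of each fixed gene list minus the median of all tested genes (horizontal axis) in 4 comparisons, with the number of tested genes in parentheses and filled symbols where the set passed with the preset correlation. Macrophage and leukocyte genes lie at log2 -2.25 and -2.33 in the sh-PRDM16 comparisons and cell cycle genes at 0.85 and 0.94, and 0 of the sets passed with an estimated correlation.

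The overlap of rosiglitazone-responsive genes with genes that differed by shRNA in treated cells compares RNA levels, and a lower level is not a smaller response to the drug. Of the 483 genes that rose with rosiglitazone in sh-scr cells, 135 were lower in treated sh-PRDM16 than in treated sh-scr arrays, Ucp1, Cidea, Cox8b, Cox7a1, Ppargc1a, Pdk4 and Ehhadh among them, and 20 were higher. Of the 2991 that fell, 615 were higher and 87 lower. Independent lists would give 22.3 and 316 for the opposite directions. The treated sh-scr arrays enter both comparisons with opposite sign, which alone, in simulated unchanged groups, gave a covariance of -0.0160 across genes against the observed -0.0788, a difference of -0.0628, with an observed r of -0.395 and a simulated r of -0.502. A split of the shared group would leave 1 array for each comparison and was not made, so part of the excess over independent lists can come from the shared arrays. The 135 genes became 64, 71 and 74 without treated sh-scr replicate 2, treated sh-scr replicate 1 and treated sh-PRDM16 replicate 1, 78 without untreated sh-scr replicate 1, 208 with a trended variance prior, 207 with a pseudocount of 64, 525 with quantile normalization and 544 on median-centred arrays, where independent lists would give 162. The 615 became 403 and 109 without treated sh-scr replicate 1 or 2, 253 and 144 without treated sh-PRDM16 replicate 1 or 2, and 243 and 221 without untreated sh-scr replicate 1 or 2. They became 1418 with a trended variance prior, 1259 with 50% of genes filtered, 1205 with a pseudocount of 64, 252 with no filter on low values and 383 on median-centred arrays, where independent lists would give 136.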

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

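The test of the second macrophage list was chosen before its result was seen, and the other tests weighed here, those of array scaling, labelling, hybridization, adipocyte content and the floor, only after the results were seen. The floor test also replaced an earlier version after that version's value was seen.

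The response to rosiglitazone differed between the sh-scr and sh-PRDM16 lines for 62 genes by the interaction term of limma, the sh-PRDM16 response being more negative for 6 and more positive for 56. Among the more negative, Ucp1 differed by log2 -3.15 (adjusted p = 0.0094, and 0.0357 on median-centred arrays), Cidea by -2.59 (0.0094 and 0.0216), Lama5 by -2.06 (0.0094 and 0.0357) and Arhgap20 by -1.22 (0.0331 and 0.0357). 2610528A11Rik differed by -2.92 and Mapk13 by -1.18 on the deposited scale, and neither passed on median-centred arrays (adjusted p = 0.0814 and 0.0726). Lama5 did not pass with quantile normalization (adjusted p = 0.0520) or as the mean of its probe sets (-0.70, adjusted p = 0.202), and had adjusted p = 0.0562 without the filter on low values, 0.0530 with a pseudocount of 1 and 0.0940 without untreated sh-PRDM16 replicate 2. Arhgap20 did not pass without the filter (adjusted p = 0.0990), with a pseudocount of 1 (adjusted p = 0.0656) or in 7 of the 8 fits without 1 array (adjusted p from 0.0547 to 0.103), and passed without treated sh-scr replicate 1 (adjusted p = 0.0468). Of the more positive, Dgat2 differed by 1.61 and passed on median-centred arrays (adjusted p = 0.0216), but not without the filter on low values (adjusted p = 0.0562) or without untreated sh-PRDM16 replicate 2 (adjusted p = 0.0900).

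The other more positive genes that were named did not pass on median-centred arrays. They were Cidec at log2 1.24, Orm1 at 1.42, Elovl3 at 1.48, Etv4 at 1.82, Cacnb1 at 1.83, S100a8 at 1.87, Wnk4 at 1.88, Dusp9 at 1.92, Tnmd at 1.94, Apoc4 at 2.05, Acot3 at 2.06, Mtarc1 at 2.13 and Scgn at 2.36, with adjusted p from 0.0094 to 0.0445 on the deposited scale and from 0.0606 to 0.197 on median-centred arrays. Wnk4 passed with quantile normalization (adjusted p = 0.0484).

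Macrophage and leukocyte genes were lower in both sh-PRDM16 groups. Array scaling is argued against as the whole cause, since the list median relative to all genes, which no shift common to an array changes, was log2 -2.25 in the condition with the smaller fall. Fewer macrophages in the sh-PRDM16 cultures may account for it: a second list with no gene in common with the first, 25 of 38 genes tested, had a median of -1.23 relative to all genes without rosiglitazone (19 fell, 0 rose) and -1.47 with it (16 fell, 0 rose). Arhgdib (-0.00 and 0.02), Cx3cr1 (-0.15 and 0.55), Fcgr2b (-0.12 and -0.40), Ptpn6 (0.19 and -0.60) Aif1 (-0.60 and -0.41), Ccr1 (-0.55 and -0.28) and, in the first list, Csf1r (-0.36 and 0.06) did not pass in either condition. Lower expression per macrophage, an effect of PRDM16 itself, an off-target effect of the single shRNA and a difference between the cultures other than the shRNA stay open and were not tested.

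Signal over all genes was lower in treated than in untreated sh-scr arrays, by a median of log2 -0.31. Labelling may account for part of it, as 12 probe sets of the poly-A control RNAs were lower in treated sh-scr arrays. A fall of these controls does not by itself speak for lower RNA input, which stays open. The poly-A array medians were 6.53 and 6.73 in treated against 7.26 and 6.98 in untreated sh-scr arrays, a difference of -0.50 (SE 0.17). Within each pair of replicates the order was the opposite of that of the genes. Treated replicate 2 had the lower median over all probe sets (6.87 against 6.95) and the higher poly-A median. The same held for untreated replicate 1 (7.16 against 7.24). In sh-PRDM16 arrays low signal came without such low poly-A medians. Untreated replicate 2 and treated replicate 1 had medians over all probe sets of log2 6.92 and 6.97, near treated sh-scr replicate 1 (6.95). Their poly-A medians were 6.98 and 7.16. RNA integrity was not tested as a cause: beta-actin 3′ minus 5′ was highest in the treated sh-scr arrays (log2 0.38 and 0.49), Gapdh in treated sh-PRDM16 replicate 2. For hybridization or scanning, 9 probe sets of hybridization controls differed by -0.076 (SE 0.11), too near to both 0 and the shift of the genes to decide. A change in the RNA content of treated cells, which the design holds as the drug, stays open and was not tested.

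Ucp1 and Cidea rose less with rosiglitazone in sh-PRDM16 cells. Array scaling is argued against, since the difference for Cidea, the smaller, was log2 -2.90 on median-centred arrays and both passed there and with quantile normalization. For fewer adipocytes, the test compared levels in treated sh-PRDM16 with those in treated sh-scr arrays. A lower level is not a smaller response to the drug, so the test cannot decide the cause of the smaller rise. It bears only on the lower levels of Ucp1 and Cidea in treated cells, provided that both fall in step with general adipocyte genes. The median of 23 general adipocyte genes in treated arrays was -0.43 relative to all genes (bootstrap SE 0.07, 5 of the 23 below -1). Not taken relative to all genes, it was -0.28 (3 below -1), with Ucp1 at -3.63 and Cidea at -3.54. The bootstrap resampled genes, which are not independent replicates (estimated correlation 0.62 in this list), so its SE can be too small. Fabp4 and Adipoq, members of the list, lay near the top of the range of the arrays, where a fall can be understated. Fewer adipocytes stay open as a cause of the smaller rise. Less differentiated adipocytes stay open too, since Ucp1 and Cidea may depend on differentiation more steeply than general adipocyte genes. Without rosiglitazone 19 of the 23 fell with sh-PRDM16, with a median of -0.82 relative to all genes. For the floor in untreated arrays, a pseudocount of 1 left -1.31 for Cidea and -2.61 for Ucp1 (adjusted p = 0.164 for both, against 0.0094 with 16), so the size of the difference is left open by values near the floor. An effect of PRDM16, an off-target effect of the shRNA and a difference between the lines stay open and were not tested.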

How the results depend on the processing

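Each test here was chosen before the results were seen. The cause of a change was not tested unless a setting's construction shows it. With an estimated correlation 0 of the 105 set tests passed (12 at an unadjusted p under 0.05), brown-fat-selective genes keeping their medians of log2 1.08 with rosiglitazone in sh-scr cells (adjusted p = 0.241) and -0.56 with sh-PRDM16 in treated cells (adjusted p = 0.395). Quantile and median-centred arrays gave 2322 and 2287 genes for sh-PRDM16 with rosiglitazone, 2487 and 2264 for rosiglitazone in sh-PRDM16 cells, 5 and 5 for the interaction, and 525 and 544 genes up with rosiglitazone and down with sh-PRDM16. No filter on low values gave 803 genes for sh-PRDM16 with rosiglitazone, 0 for the interaction in limma (2402 unadjusted), and r = 0.607 between the rosiglitazone responses, and filtering 50% of genes gave an interaction count of 1037 and r = 0.853. A trended prior gave 2609, 2005 and 1297 genes for sh-PRDM16 with rosiglitazone, rosiglitazone in sh-PRDM16 cells and the interaction, and an overlap of 208. A pseudocount of 1 gave an interaction count of 12 and r = 0.671. A pseudocount of 64 gave 2401 genes for sh-PRDM16 with rosiglitazone, an interaction count of 794, r = 0.775 and an overlap of 207. Of the 1037, 1297 and 794 interaction calls, 98.8, 98.1 and 96.5% were more positive in sh-PRDM16 cells. That is the direction of the median difference over all genes, log2 0.33 in the main setting. The filter on 50% of genes left out Ucp1 and Cidea.

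Leaving out each array in turn, the lone array being assumed to vary like the other groups, gave 1084 to 3943 genes for rosiglitazone in sh-scr cells, 492 to 1804 and 665 to 1747 for sh-PRDM16 with and without rosiglitazone, 641 to 1166 for rosiglitazone in sh-PRDM16 cells, 0 to 73 for the interaction (0 without untreated sh-PRDM16 replicate 2, 1453 unadjusted), r from 0.692 to 0.720 and an overlap of 64 to 163. Opposite directions were seen for interferon response genes without an untreated sh-PRDM16 array. Their median relative to all genes ran from -0.52 to 0.49 for sh-PRDM16 without rosiglitazone, from -0.46 to 0.20 for rosiglitazone in sh-PRDM16 cells and from -0.82 to 0.13 for the interaction. fry, which does not compare a list with other genes, gave the direction opposite to that of camera in 2 tests that passed in either. Skeletal muscle genes without rosiglitazone (median -0.10) were down in fry (adjusted p = 0.0147) and up in camera (adjusted p = 0.816), and interferon response genes in the interaction (median -0.32) up in fry (adjusted p = 0.651) and down in camera. With 50% of genes filtered the brown-fat-selective list lost its call in the interaction (adjusted p = 0.331), the direction of the test being opposite while the median stayed negative (-0.044). Fabp4 turned with rosiglitazone in sh-scr cells as the mean of its probe sets (0.47). Replicate numbers did not pair the arrays, with r from -0.02 to 0.05 over 6 pairs of groups, and as a block they left each count within 1.5 times. Of named genes, 450 of their results kept direction and side of the threshold on median-centred arrays, 39 were lost and 18 gained. With no detection calls, signal over background was not measured, and values near the floor limit fold changes.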

Other observations

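The comparison of brown-fat-selective with general adipocyte genes was a test chosen only after the result was seen, and the other values here are given without a test of their own.

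Krt19 and Acta1 moved in several comparisons. Krt19, a keratin of simple epithelia, rose by log2 0.82 and 1.74 with rosiglitazone in sh-scr and sh-PRDM16 cells, and by 0.93 and 1.85 with sh-PRDM16 without and with the drug. Acta1, skeletal muscle actin, fell by 1.33 with rosiglitazone in sh-scr cells and rose by 0.78 and 1.77 with sh-PRDM16. Neither list as a set passed in camera in these comparisons. In fry the skeletal muscle list passed as down with rosiglitazone in sh-scr cells (adjusted p = 0.0011) and with sh-PRDM16 without the drug (adjusted p = 0.0147). It passed as up with sh-PRDM16 in treated cells (adjusted p = 0.0021). The mesothelial and epithelial list passed in fry only with sh-PRDM16 in treated cells (up, adjusted p = 0.0435).

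Interferon response genes differed between the arrays of 1 group. Replicate 2 minus replicate 1 of the untreated sh-PRDM16 arrays gave a median of log2 0.78 relative to all genes, with 26 of 26 genes above the median of all genes. In the untreated sh-scr, treated sh-scr and treated sh-PRDM16 arrays the value was 0.04, -0.03 and 0.07.

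A hypothesis was that brown-fat-selective genes were lowered more than general adipocyte genes in treated sh-PRDM16 cells. The medians of 26 and 23 genes were log2 -0.40 and -0.28, a difference of -0.12 (two-sided permutation test across genes, p = 0.480), with 7 and 3 genes below -1, none of these values being taken relative to all genes. The test did not settle the hypothesis, and genes are not independent replicates.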
